A study of Mus musculus with 9 samples.

How the data were processed

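RNA was sequenced from whole lungs of mouse embryos at E18.5. Per the labels there were 9 libraries in 3 groups of 3: wild type, Dnmt1 conditional knockout (CKO) with a weak phenotype, and Dnmt1 CKO with a strong phenotype. The mutants carried Tbx4-rtTA and Tet-O-Cre with the genotype Dnmt1-D/D. Total RNA was isolated with Trizol and spin columns with an on-column DNase step, and TruSeq libraries were read as single reads of 75 nt at a stated 50 M reads per sample. Libraries are named as in their titles: WT for wild type, MUT_W for weak CKO and MUT_S for strong CKO, followed by a number shared across groups (265, 268, 549 or 860), here called the library number, and a last digit. The meaning of these numbers was not given in the sources used here. The labels did not state that each lung came from a separate litter, so p-values measure the spread between these 9 samples.

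A single table deposited by the authors was used. Its whole-number columns held counts deposited by the authors, 1 column per library, not normalised. A second set of 9 columns held RPKM values per the file headers, which equalled the count divided by the deposited gene length and by a library size 1.03 to 1.13 times the column total. The gene length was deposited by the authors, in bases. Per the submitters' processing notes, FastQC 0.11.8, cutadapt 2.5, Trimmomatic 0.36, STAR, edgeR 3.28.1 and the GRCm38.p6 genome were used. The counting tool, the annotation release, the strandedness of the libraries and the handling of reads that map to several places were not given in the sources used here. Counts of overlapping, antisense or paralogous genes are uncertain for that reason.

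Column totals ran from 25607595 to 33156732 counts. The floor used for a gene without wild type reads was 3 counts over the 3 wild type libraries, or 0.0327 CPM (the usual unit of counts scaled to library size). Against it a rise is given as at least N-fold, and with 1 to 3 wild type counts the ratio of counts is given with its 95% counting interval. Intervals and floors cover counting error only. Of 27207 genes in the table, 19374 passed filterByExpr by group, and 1 had 0 counts in every library. The common biological coefficient of variation was 0.15. Genes were placed on GRCm38 by Ensembl identifier; 27197 of the 27207 identifiers were found on the same chromosome and strand in the GENCODE annotation used.

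Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the counts, with TMM factors (0.938 to 1.04), 1 mean per group, a robust quasi-likelihood fit of all 9 libraries and two-sided quasi-likelihood F tests. The contrasts were weak CKO against wild type, strong CKO against wild type, strong CKO against weak CKO, and the mean of both CKO groups against wild type. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Errors of log2 changes are standard errors derived from the unshrunk change and its F statistic. Values per library are TMM-normalised CPM, and log2 CPM used a prior count of 2. An exact permutation test of 3 libraries against 3 cannot give p below 0.1, so no single-gene permutation test was used.

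The tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined, apart from what is stated otherwise. Genes named were Dnmt1; the 8 largest rises and 8 largest falls per contrast among genes with adjusted p under 0.05, a mean log2 CPM of at least 1, no overlap between the libraries of the groups and an informative symbol; up to 4 called members with the smallest adjusted p of each list described, or up to 2 members with the highest abundance where none was called; 4 haemoglobin genes; and Xist and Ddx3y. A gene outside this rule is said to have been picked afterwards.

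The lists numbered 31 and held 501 genes: DNA methylation machinery, germline genes known to be silenced by promoter DNA methylation, imprinted genes, p53 target genes, interferon-stimulated genes, cell cycle genes, alveolar type 2 epithelium, alveolar type 1 epithelium, airway epithelium, smooth muscle and myofibroblast contractile genes, elastic fibre and collagen genes, lung mesenchyme and lipofibroblast genes, lung branching and growth signals, endothelium, capillary endothelium, lymphatic endothelium, pericytes, mesothelium, cartilage, erythroid cells, platelets and megakaryocytes, macrophages and monocytes, neutrophils, lymphocytes, hypoxia and glycolysis, heme and iron handling, inflammatory cytokines and adhesion molecules, striated muscle, nerve and Schwann cells, sex-linked genes, and liver plasma proteins. Of the listed genes, 8 had no match in the table (Bpifa1, Ccl21a, Snorc, Ucma, Ahsp, Gp1bb, Fgb and Fga) and were not analysed here. The symbol Aldoa matched 2 identifiers, so the 20 hypoxia and glycolysis genes gave 21 tested entries. A list needed 3 tested members, and the liver plasma protein list, which fell short of that, was not tested. Each of the other 30 lists was tested with camera (limma 3.58.1) at the preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a contrast. The p-values given for lists are camera adjusted p-values with the preset correlation unless stated otherwise.

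The correlation and covariance of changes in both comparisons with wild type were set against 20 simulated draws in which unchanged groups shared the same simulated controls. Recovery was tested on simulated data of the same size and dispersion, with 66 or 67 genes changed at each fold in each contrast. Changed genes were drawn above a minimum abundance. The shares recovered may therefore be lower for scarcer genes, and also in a contrast where few genes change. Of genes changed 1.5-fold, 2-fold and 4-fold, 53.7%, 83.6% and 95.5% were recovered in the weak contrast, 50.7%, 82.1% and 95.5% in the strong contrast, and 61.2%, 80.6% and 90.9% between the CKO groups. A changed list was called and 0 of 29 unchanged lists were. The simulated genes varied independently of each other, so this does not test false calls for lists whose members are correlated.

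Alternatives were RLE and upper quartile factors, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, erythroid genes left out before normalisation, the erythroid level as a covariate, the library number as a block, a fit of only the groups compared, DESeq2 1.42.0, limma-trend on log2(RPKM + 1) and on log2(RPKM + 0.1), and leaving out each of the 9 libraries in turn. For the overlap, a threshold of 0.01 was also tried. The level of Y-linked genes as a covariate, and leaving out genes of chromosomes X and Y, were added after the data were seen. Raw reads and the deposited RPKM values, apart from the alternatives that name RPKM, were not used here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.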

Results

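Gene expression was measured by RNA sequencing in whole lungs of mouse embryos at E18.5, shortly before birth. Dnmt1 encodes the methyltransferase that copies DNA methylation marks onto newly made strands. In the mutants it was deleted by a Cre recombinase under Tet-O control with a Tbx4-rtTA driver, a combination used to target lung mesenchyme. The 9 libraries came from 3 wild type lungs, 3 Dnmt1 conditional knockout (CKO) lungs with a weak phenotype, which were hypoplastic, and 3 CKO lungs with a strong phenotype, which were hypoplastic and bled widely into the parenchyma. Libraries are named as in their titles, WT for wild type, MUT_W for weak CKO and MUT_S for strong CKO. Total counts were 30562772 in WT_265_1, 31785040 in WT_268_1 and 32485816 in WT_549_2. They were 29603791 in MUT_W_265_2, 33156732 in MUT_W_268_3 and 31496025 in MUT_W_549_3, and 25607595 in MUT_S_265_5, 27334378 in MUT_S_268_4 and 29420807 in MUT_S_860_3. Of 27207 genes, 19374 had enough counts to be tested. The first principal component held 59.1% of the variance and set the wild type libraries (−76 to −66.5) apart from all 6 CKO libraries (14.4 to 49.4). The genes with the most counts, named after the data were seen, were the surfactant gene Sftpc in 7 libraries, the mitochondrial gene mt-Co1 in MUT_S_265_5 and the haemoglobin gene Hbb-bs in MUT_S_860_3.

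Dnmt1 (ENSMUSG00000004099, chromosome 9, 20907209 to 20959888 in GRCm38) was present in every library. WT_265_1, WT_268_1 and WT_549_2 held 79.1, 121 and 97.2 CPM, MUT_W_265_2, MUT_W_268_3 and MUT_W_549_3 held 59.1, 69.1 and 80.6 CPM, and MUT_S_265_5, MUT_S_268_4 and MUT_S_860_3 held 62, 78.7 and 65.1 CPM. Group means were 99.1 ± 21.0 CPM in wild type, 69.6 ± 10.8 CPM in weak CKO and 68.6 ± 8.91 CPM in strong CKO (SD, n = 3 each). Dnmt1 fell in strong CKO (log2 change −0.53 ± 0.17, SE; adjusted p = 0.0433). In weak CKO the change was −0.51 ± 0.17 and was not called (adjusted p = 0.0727). Both adjusted p-values lay near the threshold. The strong CKO call ended without WT_268_1 (−0.36) or WT_549_2 (−0.54), MUT_W_268_3 (−0.52), or MUT_S_265_5 (−0.46) or MUT_S_860_3 (−0.49), and with upper quartile factors (−0.51), no filter (−0.52), only the groups compared (−0.53), log2(RPKM + 1) (−0.38) and log2(RPKM + 0.1) (−0.49). The weak CKO call appeared without WT_265_1 (−0.65) or MUT_W_549_3 (−0.63), with the library number as a block (−0.50) and in DESeq2 (−0.52). The count covers the whole gene in whole lung, and which exons the deletion removes was not given in the sources used here, so it does not measure the share of cells that lost the gene. Among 13 tested genes of the DNA methylation machinery, 1 rose and 4 fell in strong CKO (1 and 5 adjusted over the list alone), among the falls the demethylase Tet1 (−0.38, or −0.18 on the log2(RPKM + 1) scale) and the methyl-CpG reader Mbd2 (−0.26). In weak CKO 0 rose and 1 fell, the same counts as adjusted over the list alone. It was Mbd2 (−0.22), a call that ended without WT_265_1 (−0.19), WT_549_2 (−0.24), MUT_W_265_2 (−0.21), MUT_W_268_3 (−0.19), MUT_S_268_4 (−0.22) or MUT_S_860_3 (−0.22). It also ended with no filter (−0.22), only the groups compared (−0.22), or the erythroid (−0.16) or Y-linked (−0.23) level as a covariate. The list as a whole was not called in weak CKO (adjusted p = 0.557) or in strong CKO (adjusted p = 0.287).

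The first comparison asked what the lungs without haemorrhage expressed differently from wild type. Genes of the germline came on. These genes carry methylated promoters in somatic tissue, and 22 of the 24 listed rose, with 22 also up when adjusted over the list alone. The exceptions, named after their values were seen, were the synaptonemal complex gene Sycp3 (0.46) and the piRNA pathway gene Tdrd1 (−0.54). Dazl, which encodes an RNA-binding protein of germ cells (ENSMUSG00000010592, chromosome 17, 50279395 to 50293636), rose from 0.251 ± 0.0369 to 202 ± 49.9 CPM (log2 change 9.63 ± 0.33, SE; adjusted p = 1.45e-06). The X-linked transcription factor gene Taf7l went from 0.0523 to 54.3 ± 13.2 CPM (9.86 ± 0.44), and Sohlh2, a regulator of germ cell differentiation on chromosome 3, from 0.0423 to 45.1 ± 13.9 CPM (9.89). Stag3, a meiotic cohesin gene with some wild type expression, rose from 3.22 ± 0.647 to 44.5 ± 4.02 CPM (3.78). The piRNA helicase gene Mov10l1 rose from 0.151 to 14.9 ± 3.30 CPM (6.57). Among the other largest rises were genes without a single wild type read. Against the floor, Pet2 on chromosome X was at least 1270-fold higher (41.4 ± 8.96 CPM), Tex19.1 at least 550-fold (17.97 ± 6.61 CPM), Tex101 at least 364-fold and the X-linked protease gene Usp26 at least 322-fold. The tubulin gene Tuba3a had 1 wild type count, which gave a ratio of 824 with an interval of 147 to 32600, and its reads cannot be separated with certainty from those of its near-identical paralog Tuba3b. The median log2 change of the germline list was 5.42 (25th to 75th percentile 4.05 to 7.92), and 5.01 with the 7 genes at or under the wild type floor set to their bound. Its test gave an adjusted p of 2.04e-95, and 0.034 with an estimated correlation, which made it the only list of 30 to hold under both. On the log2(RPKM + 1) scale, which compresses genes of low abundance, the change was 4.40 for Dazl, 3.78 for Taf7l, 4.13 for Sohlh2, 1.37 for Stag3, 1.17 for Mov10l1, 2.45 for Pet2 and 2.66 for Tuba3a, all still called. Adding 0.1 to RPKM in place of 1 left changes between the smaller and the larger value, such as 3.60 for Mov10l1 and 5.69 for Tuba3a.

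**Figure D1:**
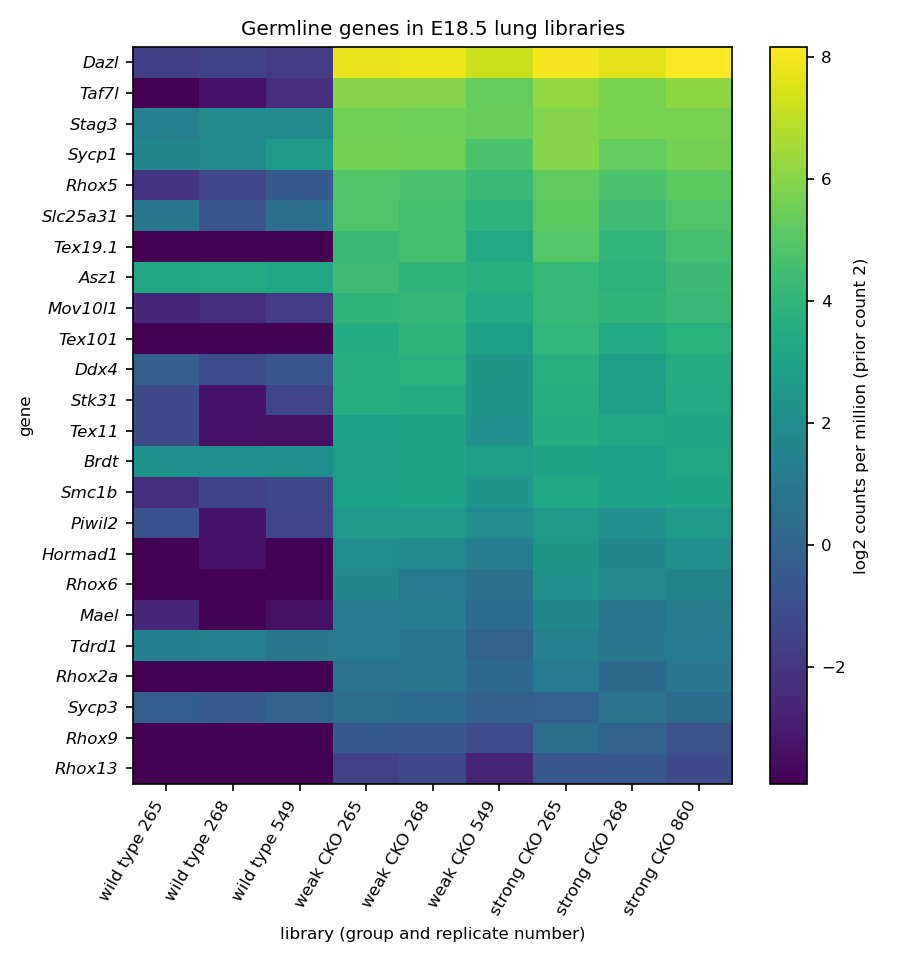
Log2 CPM (colour) of the 24 listed germline genes (vertical) in each of the 9 libraries (horizontal, by group). In both CKO groups 22 of the 24 were higher than in wild type, and Sycp3 and Tdrd1 were not called.

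Lung mesenchyme and blood vessel genes were lower in weak CKO. Of 18 lung mesenchyme and lipofibroblast genes 6 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of −0.42 and an adjusted p of 2.08e-08 (0.44 with an estimated correlation). They included Wnt2, a mesenchymal signal for lung growth (ENSMUSG00000010797, chromosome 6, 17988940 to 18030585), which went from 72.8 ± 2.74 to 33.6 ± 5.29 CPM (−1.11 ± 0.13; adjusted p = 0.000477), Limch1 (−0.86), the platelet-derived growth factor receptor gene Pdgfra (−0.57) and the transcription factor gene Tbx2 (−0.62). Of 18 endothelial genes 10 fell (16 adjusted over the list alone; median −0.41, adjusted p = 1.05e-07, 0.50 with an estimated correlation), among them Sox17, which specifies arterial endothelium (108 ± 16.5 to 68.7 ± 5.02 CPM, −0.65 ± 0.11). Of 10 capillary genes 3 fell (6 adjusted over the list alone; median −0.36, adjusted p = 0.00602, 0.50 with an estimated correlation). The complement gene C7 (43.4 ± 11.4 to 8.28 ± 1.81 CPM, −2.39 ± 0.24; adjusted p = 0.000282), the sulfate transporter gene Slc13a4 (10.3 ± 3.76 to 1.61 ± 0.592 CPM, −2.69 ± 0.34), Shisa6 (−2.24), Aspa (−2.23), Col6a4 (−2.22) and Pcdh20 (−2.08) were among the 8 largest falls and were called at every setting. On the log2(RPKM + 1) scale these changes were −0.99 for Slc13a4, −0.84 for Shisa6, −0.55 for Aspa, −0.71 for Col6a4 and −0.79 for Pcdh20. Of 19 erythroid genes 3 fell (5 adjusted over the list alone; median −0.51, adjusted p = 0.000242, 0.63 with an estimated correlation). Of 14 alveolar type 1 genes 0 were called (median −0.18), and the adjusted p of that list was 0.043 (0.78 with an estimated correlation). That list was no longer called without WT_265_1 (−0.08), MUT_W_268_3 (−0.12) or MUT_W_549_3 (−0.15), or MUT_S_265_5, MUT_S_268_4 or MUT_S_860_3 (−0.18 each), or with the Y-linked level as a covariate (−0.18). Of 13 alveolar type 2 genes 2 fell (2 adjusted over the list alone; median −0.18, adjusted p = 0.0644).

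Airway, macrophage, inflammatory and nerve gene lists were higher in weak CKO. Of 13 airway epithelial genes 5 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.81, adjusted p = 6e-07, 0.44 with an estimated correlation). The secretoglobin gene Scgb3a2 (ENSMUSG00000038791, chromosome 18, 43764289 to 43767399) went from 647 ± 108 to 1426 ± 202 CPM (1.14 ± 0.16; adjusted p = 0.00128), and the ciliary genes Foxj1 (0.80 ± 0.15), Rsph1 (0.84 ± 0.07) and Tekt1 (0.76) rose with it. Of 18 macrophage and monocyte genes 7 rose (11 adjusted over the list alone; median 0.67, adjusted p = 3.27e-06, 0.52 with an estimated correlation), among them the complement genes C1qa (1.14), C1qb (1.17) and C1qc (1.11). Of 16 inflammatory genes 7 rose (10 adjusted over the list alone; median 1.0, adjusted p = 1.14e-06, 0.50 with an estimated correlation). The acute phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) went from 1.87 ± 0.899 to 138 ± 46.9 CPM (6.20 ± 0.41; adjusted p = 7.52e-05) and the monocyte attractant gene Ccl2 from 0.487 to 6.62 ± 1.21 CPM (3.75 ± 0.46, or 1.75 on the log2(RPKM + 1) scale). Of 11 nerve and Schwann cell genes 5 rose (6 adjusted over the list alone; median 0.90, adjusted p = 0.00864, 0.32 with an estimated correlation), including Sox10 (2.03) and Tubb3 (2.28), at 0.13 and 0.33 on the log2(RPKM + 1) scale. Of 12 heme and iron genes 4 rose (7 adjusted over the list alone; median 0.36, adjusted p = 0.00422, 0.52 with an estimated correlation), including the haptoglobin gene Hp (1.11) and the heme oxygenase gene Hmox1 (24.9 ± 2.22 to 68.4 ± 30.8 CPM, 1.46 ± 0.36; adjusted p = 0.0329). The Hmox1 call ended without WT_265_1 (1.54), WT_268_1 (1.42), WT_549_2 (1.43), MUT_W_268_3 (1.09) or MUT_W_549_3 (1.47). It also ended with no filter (1.47), the erythroid level as a covariate (1.41) or the library number as a block (1.44). Of 13 striated muscle genes 4 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.80, adjusted p = 0.00653, 0.52 with an estimated correlation), a list no longer called without MUT_W_549_3 (0.65). Of 25 p53 target genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.21, adjusted p = 0.0401, 0.52 with an estimated correlation), among them Eda2r (2.02) and Gdf15 (2.33), at 0.46 and 0.32 on the log2(RPKM + 1) scale. The p53 list was no longer called without WT_268_1 (0.17), MUT_W_265_2 (0.21) or MUT_W_268_3 (0.14), with the library number as a block (0.21), or with X and Y genes left out (0.18).

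Imprinted genes moved both ways in weak CKO, 5 up and 4 down of 27 (5 and 5 adjusted over the list alone; median −0.02, adjusted p = 0.85). The maternally expressed noncoding RNA H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143) rose from 1027 ± 41 to 1973 ± 50.4 CPM (0.94 ± 0.10; adjusted p = 0.000278) and Impact rose by 0.71. Igf2r, the maternally expressed receptor gene on chromosome 17 that Airn overlaps in antisense, fell from 780 to 450 CPM (−0.80 ± 0.11; adjusted p = 0.00128). The other lists were not called in weak CKO, with adjusted p of 0.278 or more. Calls in them were 3 up and 1 down of 14 smooth muscle genes, 5 up and 1 down of 18 elastic fibre and collagen genes, 3 up and 4 down of 20 branching and growth signals, 5 up and 2 down of 16 pericyte genes, 1 up and 1 down of 6 lymphatic genes, 2 up of 11 mesothelial genes, 1 up of 10 cartilage genes, 1 up and 1 down of 21 tested entries for 20 hypoxia and glycolysis genes (Aldoa had 2 identifiers), 1 up of 25 cell cycle genes and 1 down of 13 neutrophil genes. Called genes included Mfap4 of the elastic fibres (2881 ± 296 to 1643 ± 231 CPM, −0.81) and the mesothelial gene Wt1 (0.90, or 0.24 on the log2(RPKM + 1) scale). Interferon-stimulated, platelet, lymphocyte and sex-linked genes had 0 calls among 24, 11, 9 and 6 tested members. For the interferon, mesothelium, lymphatic and cartilage lists the median was below 0 and the mean above 0 (−0.19 and 0.03, −0.06 and 0.11, −0.09 and 0.10, and −0.14 and 0.06), and the test pointed up for mesothelium and cartilage and down for the others.

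Over all genes, 2803 of 19374 were called in weak CKO, 1761 up and 1042 down. Of these, 776 rose and 188 fell more than 2-fold, and 316 rose and 6 fell more than 8-fold by the fitted change. Values of all 3 weak CKO libraries lay beyond all 3 wild type values for 6091 genes (31.4%, where chance gives 10%). The count was 1766 without WT_549_2, 1432 without MUT_W_265_2, 1310 without MUT_W_268_3 and 1452 with the erythroid level as a covariate. The erythroid level was itself lower in every weak CKO library than in every wild type library.

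**Figure D2:**
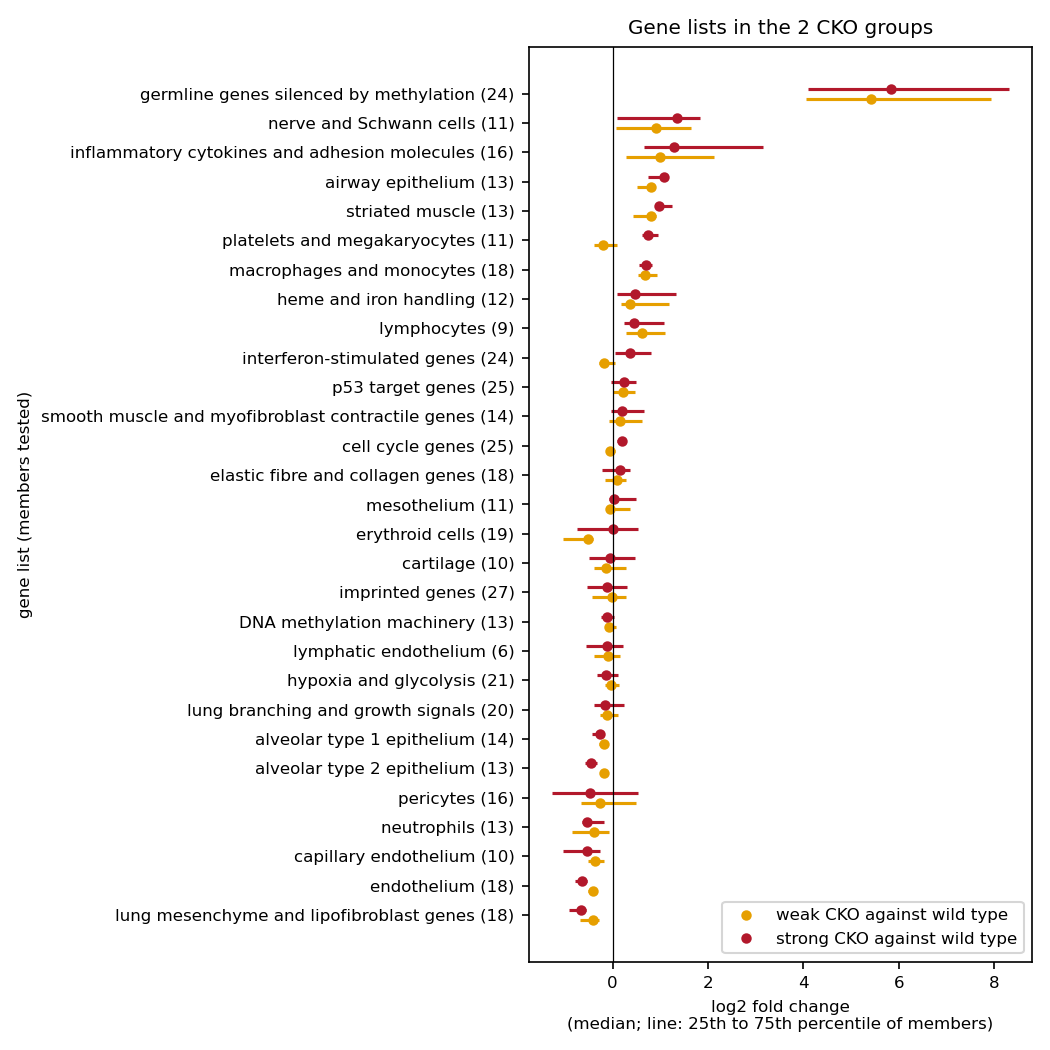
Median log2 fold change (points, horizontal axis) with the 25th to 75th percentile (bars) of 29 gene lists (vertical axis) in weak and strong CKO against wild type. The germline list sits at 5.42 and 5.84, airway at 0.81 and 1.08, and endothelium at −0.41 and −0.64.

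The second comparison asked what lungs with haemorrhage expressed differently from wild type. The germline program was on here too, with 22 of 24 genes up and 22 adjusted over the list alone (median 5.84, 25th to 75th percentile 4.10 to 8.31, or 5.21 with genes at their bound). Its test gave an adjusted p of 6.9e-77, and 0.049 with an estimated correlation. Dazl reached 249 ± 44.0 CPM (9.93 ± 0.33; adjusted p = 9.53e-07), Taf7l 65.5 ± 11.2 CPM (10.13 ± 0.43) and Stag3 55.2 ± 3.94 CPM (4.09 ± 0.14), with 4.71, 4.05 and 1.58 on the log2(RPKM + 1) scale. Pet2 was at least 1680-fold higher than the floor, Tex19.1 at least 736-fold, Tex101 at least 427-fold and Usp26 at least 386-fold. Tuba3a had a ratio of 1360 with an interval of 245 to 54000.

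Vessel, mesenchyme and alveolar genes were lower in strong CKO. All 18 endothelial genes fell (18 adjusted over the list alone; median −0.64, adjusted p = 2.78e-12, 0.25 with an estimated correlation). The vascular cadherin gene Cdh5 (ENSMUSG00000031871, chromosome 8, 104101625 to 104144511) went from 737 to 425 CPM (−0.80; adjusted p = 0.00143), Sox17 from 108 ± 16.5 to 57.6 ± 5.24 CPM (−0.90), and the angiopoietin co-receptor gene Tie1 fell by 0.79 on the log2 scale. Of 10 capillary genes 7 fell (7 adjusted over the list alone; median −0.54, adjusted p = 2.56e-05, 0.25 with an estimated correlation), among them the endothelin receptor gene Ednrb (263 to 126 CPM, −1.07). Of 18 lung mesenchyme genes 16 fell (17 adjusted over the list alone; median −0.66, adjusted p = 1.77e-12, 0.25 with an estimated correlation). Wnt2 went to 25.7 ± 4.17 CPM (−1.50; adjusted p = 5.89e-05), Limch1 to 456 CPM (−1.20) and the transcription factor gene Tcf21 from 387 to 222 CPM (−0.80). Of 13 alveolar type 2 genes 9 fell (11 adjusted over the list alone; median −0.46, adjusted p = 0.000662, 0.53 with an estimated correlation), among them the surfactant lipid gene Lpcat1 (−0.57). Of 14 alveolar type 1 genes 3 fell (6 adjusted over the list alone; median −0.26, adjusted p = 0.00486, 0.55 with an estimated correlation). The largest falls called at every setting were in Adcy8 (−3.53 ± 0.56; adjusted p = 0.00238), Slc13a4 (−3.37), Col6a4 (−2.91), C7 (43.4 ± 11.4 to 5.86 ± 1.46 CPM, −2.89), Mchr1 (−2.88) and Aspa (−2.82), of which Adcy8, Slc13a4, Col6a4, Mchr1 and Aspa stood at −0.55, −1.09, −0.81, −1.43 and −0.62 on the log2(RPKM + 1) scale. The methyltransferase gene Inmt fell further (−4.44, adjusted p = 0.0238), a size that rested in part on WT_265_1. Inmt measured 175, 15.8 and 46.1 CPM in WT_265_1, WT_268_1 and WT_549_2, and 2.26, 7.14 and 1.54 CPM in MUT_S_265_5, MUT_S_268_4 and MUT_S_860_3. The call ended without MUT_S_265_5 (−4.19) or MUT_S_860_3 (−4.05), with only the groups compared (−4.43), with the library number as a block (−3.57) and with the Y-linked level as a covariate (−3.41).

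Airway, inflammatory, macrophage, muscle and nerve genes were higher in strong CKO. Of 13 airway genes 8 rose (11 adjusted over the list alone; median 1.08, adjusted p = 1.42e-08, 0.25 with an estimated correlation), with Scgb3a2 at 1635 ± 271 CPM (1.34; adjusted p = 0.000321), Foxj1 at 133 CPM (1.17) and Rsph1 at 37.9 ± 1.86 CPM (1.08). Of 16 inflammatory genes 12 rose (14 adjusted over the list alone; median 1.29, adjusted p = 1.51e-09, 0.32 with an estimated correlation), with Saa3 at 126 ± 20.7 CPM (6.07; adjusted p = 6.13e-05), Ccl2 at 16.2 ± 7.71 CPM (5.03, or 2.72 on the log2(RPKM + 1) scale) and the adhesion gene Icam1 at 188 CPM (0.52). Of 18 macrophage genes 10 rose (12 adjusted over the list alone; median 0.70, adjusted p = 7.11e-05, 0.55 with an estimated correlation), among them C1qc (43.2 ± 8.80 CPM, 1.26). Of 12 heme and iron genes 7 rose (7 adjusted over the list alone; median 0.47, adjusted p = 0.00129, 0.44 with an estimated correlation). Hmox1, which encodes the heme-degrading enzyme (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), went from 24.9 ± 2.22 to 169 ± 48.8 CPM (2.76 ± 0.37; adjusted p = 0.00166), a call that ended with the library number as a block (2.57). The ferritin gene Fth1 rose by 0.45. Of 13 striated muscle genes 9 rose (11 adjusted over the list alone; median 0.97, adjusted p = 0.00032, 0.41 with an estimated correlation), among them the cardiac myosin genes Myh6 (1.24) and Myl4 (1.10). Of 11 nerve genes 6 rose and 0 fell (7 and 2 adjusted over the list alone; median 1.34, adjusted p = 0.00424, 0.24 with an estimated correlation), among them Prph (3.39, or 0.55 on the log2(RPKM + 1) scale).

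The remaining lists were not called in strong CKO. Imprinted genes again moved both ways, 6 up and 7 down of 27 (6 and 12 adjusted over the list alone; median −0.11, adjusted p = 0.584), with H19 at 2461 ± 315 CPM (1.26; adjusted p = 3.31e-05) and Igf2r at 367 CPM (−1.09). Of 25 p53 targets 8 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.23, adjusted p = 0.068). Of 16 pericyte genes 5 rose and 9 fell (5 and 11 adjusted over the list alone; median −0.47, adjusted p = 0.0817), including Heyl (1.64) and Ndufa4l2 (−1.29). Of 20 branching and growth signals 4 rose and 6 fell (5 and 9 adjusted over the list alone; median −0.17, adjusted p = 0.102), including the Hedgehog inhibitor gene Hhip (−1.09). Of 25 cell cycle genes 2 rose (2 adjusted over the list alone; median 0.19, adjusted p = 0.156), including Cdc20 (0.80). Calls in the others were 4 up and 1 down of 14 smooth muscle genes, 6 up and 4 down of 18 elastic fibre and collagen genes, 1 up and 2 down of 6 lymphatic genes, 3 up of 11 mesothelial genes, 2 up of 10 cartilage genes, 2 down of 19 erythroid genes, 1 up and 1 down of 11 platelet genes, 1 up and 1 down of 13 neutrophil genes, 1 up and 5 down of the 21 hypoxia and glycolysis entries, 0 of 9 lymphocyte genes and 0 of 6 sex-linked genes. Mfap4 went to 1317 CPM (−1.13), Col1a2 rose by 0.56 and the hypoxia-responsive gene Adm went from 8.25 to 2.41 CPM (−1.77). Of 24 interferon-stimulated genes 1 rose, the chemokine gene Cxcl10 (5.85 ± 1.08; adjusted p = 0.00621; 1.20 and not called on the log2(RPKM + 1) scale), which measured 4.59, 2.43 and 21.9 CPM in MUT_S_265_5, MUT_S_268_4 and MUT_S_860_3. The lymphatic and cartilage lists had medians below 0 (−0.11 and −0.06) and means above 0 (0.06 and 0.08), with tests pointing down and up.

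In strong CKO 4969 genes were called, 2830 up and 2139 down, of which 1197 rose and 407 fell more than 2-fold and 344 rose and 19 fell more than 8-fold. The groups did not overlap for 8083 genes (41.7%, where chance gives 10%). The count was 3101 without MUT_S_265_5 and 2914 with the Y-linked level as a covariate.

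The changes in both CKO groups largely pointed the same way. Of the genes called in weak CKO 94.3% were also called in strong CKO, 1684 up and 957 down in both, where independent lists would share 257 and 115, and 1 was called in opposite directions. Log2 changes across genes, which are not independent replicates, had a Pearson r of 0.94 and a covariance of 0.974. Simulated unchanged groups with the same shared controls gave a mean r of 0.50 (highest 0.60) and a covariance of 0.0911. The change was larger in strong CKO for 2147 of the 2641 shared genes (81.3%), with a median ratio of 1.16. The libraries of the CKO groups overlapped on the first principal component, at 14.4 to 35.7 in weak and 32.4 to 49.4 in strong CKO. Their direct comparison called 1 gene. The overlap of weak and strong effects was 1694 without WT_549_2, 1393 without MUT_W_265_2, 1281 without MUT_W_268_3, 1729 with the Y-linked level as a covariate and 1024 at an adjusted p under 0.01. With both CKO groups together against wild type, 5137 genes were called, 2918 up and 2219 down, and 13 of 30 lists, of which 0 held with an estimated correlation. In that contrast 22 of 24 germline genes rose (median 5.62, adjusted p = 4.25e-79, 0.052 with an estimated correlation), all 18 endothelial genes fell (median −0.51, adjusted p = 0.31 with an estimated correlation) and 13 of 16 inflammatory genes rose (median 1.26, adjusted p = 0.40 with an estimated correlation). Median and mean differed in sign for the mesothelium, lymphatic and cartilage lists.

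The direct comparison of strong with weak CKO asked what went with the haemorrhage. Few genes passed the threshold: edgeR called 1 gene, with 1099 of 19374 at an unadjusted p under 0.05. Chance alone would give a share of about 0.05 of the genes tested. The groups did not overlap for 13.4% of genes, where chance gives 10%. The called gene was Rpl35a, which encodes a protein of the large ribosomal subunit (ENSMUSG00000060636, chromosome 16, 33056453 to 33060189). It measured 96.9 ± 4.75 CPM in wild type, 151 ± 10.9 CPM in weak CKO and 81.9 ± 6.22 CPM in strong CKO (SD, n = 3 each), a change of −0.89 ± 0.08 from weak to strong (adjusted p = 0.00623). The call held without any single library (−0.95 to −0.83) and ended with the erythroid level as a covariate (−0.86; adjusted p = 0.204). That level was lower in every weak than in every strong CKO library, so the lost call cannot be put down to blood. DESeq2 called 14 genes, a fit of only these groups 4, the library number as a block 3 and log2(RPKM + 0.1) 2. The count was 3 without WT_265_1, 2 without MUT_W_265_2, 4 without MUT_W_268_3, 3 without MUT_S_268_4 and 2 without MUT_S_860_3.

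No haemoglobin gene was called in any comparison of the groups, and the higher means of Hbb-bs, Hba-a1 and Hba-a2 in strong CKO rested in part on MUT_S_860_3. Hbb-bs, the adult beta-globin gene on chromosome 7 (103826534 to 103828096), measured 3574 ± 1135 CPM in wild type, 2575 ± 161 CPM in weak CKO and 5822 ± 2240 CPM in strong CKO, with 4610, 4450 and 8410 CPM in MUT_S_265_5, MUT_S_268_4 and MUT_S_860_3 and 4790 CPM in WT_265_1. The strong minus weak difference was 1.18 ± 0.28 and was not called (adjusted p = 0.873), nor was strong CKO against wild type (0.70, adjusted p = 0.0956), and without MUT_S_860_3 these differences were 0.82 and 0.35. Weak CKO against wild type was not called either (−0.47, adjusted p = 0.307). Means in the same order of groups were 626, 510 and 1088 CPM for Hba-a1, 410, 323 and 772 CPM for Hba-a2, and 678, 504 and 882 CPM for Hbb-bt, though reads of these near-identical pairs were divided between them in a way not given in the sources used here. The erythroid list differed by a median of 0.81 (adjusted p = 1.58e-15, 0.26 with an estimated correlation, with 7 genes up adjusted over the list alone), which went with a fall in weak CKO (−0.51 against wild type, adjusted p = 0.000242, 0.63 with an estimated correlation) while strong CKO was not called against wild type (median 0, adjusted p = 0.795). The platelet list differed by 0.83 (adjusted p = 8.18e-08, 5 up adjusted over the list alone) and the inflammatory list by 0.43 (adjusted p = 6.38e-09, 5 up). Of 30 lists 17 differed, and 0 did with an estimated correlation (lowest adjusted p = 0.26) or by fry. Lists lower in strong than in weak CKO included mesenchyme (−0.23), endothelium (−0.21) and capillaries (−0.28). The median, mean and test of 4 lists in this contrast (smooth muscle, macrophages, neutrophils and cartilage) differed in sign.

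**Figure D3:**
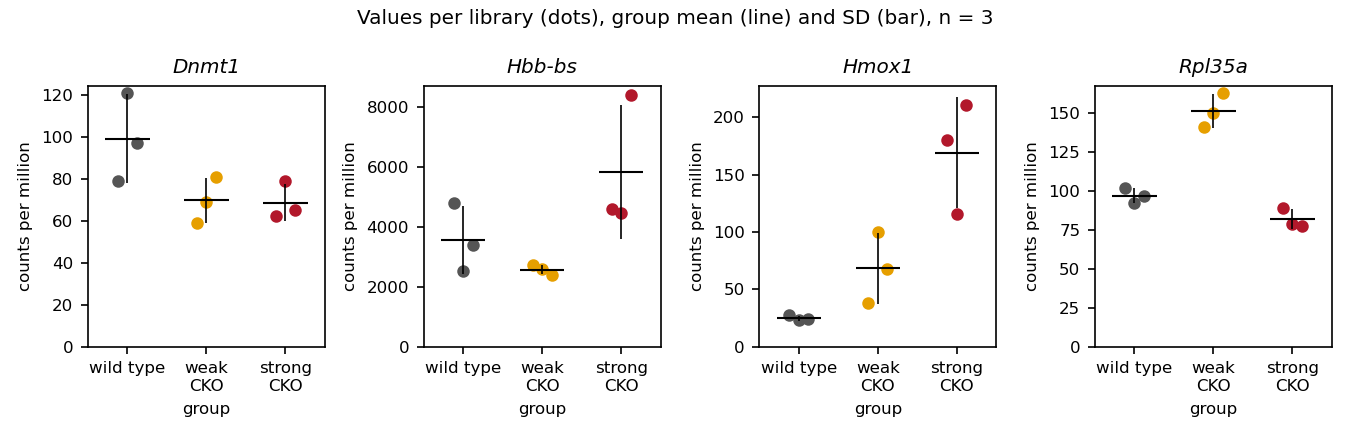
CPM (vertical axis) of Dnmt1, Hbb-bs, Hmox1 and Rpl35a in each library (points) by group (horizontal axis), with the group mean (line) and SD (bar), n = 3 each. Hbb-bs was highest in MUT_S_860_3 at 8410 CPM, and Rpl35a averaged 151 CPM in weak CKO against 96.9 and 81.9 CPM in wild type and strong CKO.

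Sex-linked genes showed that the embryos' sex was not balanced between groups. The Y-linked RNA helicase gene Ddx3y measured 165 CPM in WT_265_1, 159 CPM in WT_549_2, 166 CPM in MUT_W_268_3 and at most 0.0377 CPM in each other library, so Y-linked RNA was present in 2 wild type, 1 weak CKO and 0 strong CKO libraries. Xist, the noncoding RNA that silences an X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), measured 2.51, 2080 and 4.51 CPM in WT_265_1, WT_268_1 and WT_549_2, and 2570, 956 and 2230 CPM in MUT_W_265_2, MUT_W_268_3 and MUT_W_549_3. In strong CKO it measured 2120, 2440 and 2570 CPM. MUT_W_268_3 therefore held both Ddx3y and Xist. Xist was not called in weak CKO (1.47, adjusted p = 0.701) or strong CKO (1.77, adjusted p = 0.576), and was called in both without WT_268_1 (9.08 and 9.39). Its antisense gene Tsix, picked afterwards, lay between 0.869 and 1.8 CPM in every library.

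**Figure D4:**
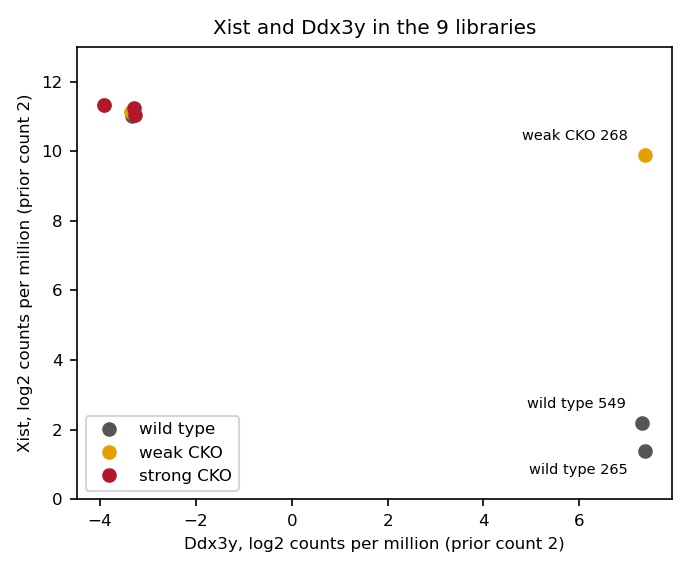
Log2 CPM of Xist (vertical axis) against Ddx3y (horizontal axis), 1 point per library, coloured by group. MUT_W_268_3 is the only library with high values of both, at 956 CPM of Xist and 166 CPM of Ddx3y.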

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

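Tests of explanations for Rpl35a and for the lists moving apart in strong CKO were set up after these patterns had been seen. Those of a smaller share of lung mesenchyme alone and of Rpl35a pseudogenes were chosen only after the result was seen. So was the Y-linked level as a covariate. Rpl35a differed between strong and weak CKO, as did 17 gene lists by camera with the preset correlation, none of which was called with an estimated correlation (lowest adjusted p = 0.26) or by fry.

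Rpl35a fell from weak to strong CKO by 0.89 on the log2 scale (−0.89) and was higher in weak CKO than in either other group. Reads moved to or from the 2 pseudogenes of Rpl35a identified among the deposited genes are argued against. The summed level of these pseudogenes differed by −0.045 CPM while Rpl35a differed by −69.5 CPM. Pseudogenes not identified there were not covered. A shift of ribosomal protein genes as a class is argued against as well, because the other 70 had a median difference of −0.01 (−0.24 to 0.39). Reads discarded for mapping to several places could still differ between libraries and remain open, as does a regulation of this gene in weak CKO, which was not tested. Among the 10 splits of the 6 CKO libraries, 3 gave at least as many genes as the real grouping, itself included (4 genes in the 6-library fit, highest other 5). The number of genes called between the CKO groups was thus no larger than other groupings of these libraries gave.

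Airway, nerve, muscle and macrophage lists were higher and endothelial, mesenchymal and alveolar type 2 lists lower in strong CKO, with all 3 strong CKO libraries beyond all wild type libraries for each of these lists. A smaller share of lung mesenchyme alone, with endothelium counted as a separate cell type, would raise every other cell type alike. This is argued against by the gap of −1.72 between the median changes of 18 endothelial and 13 airway genes, lists already seen to differ. If endothelium is counted with the mesenchyme, the gap cannot decide, but alveolar type 2 genes should then rise with airway genes. Mean log2 CPM per library of the alveolar type 2 list was 9.66 to 10.04 in wild type and 9.36 to 9.54 in strong CKO. This fall argues against that reading as the sole cause, though the alveolar type 2 list was not called with an estimated correlation. Mean log2 CPM per library was 7.44 to 7.73 in wild type and 6.83 to 7.11 in strong CKO for endothelium, and 5.43 to 5.91 and 6.7 to 6.88 for airway, while neither list was called with an estimated correlation (adjusted p = 0.25 each). The sex of the embryos is argued against as the whole cause, since the gap was −1.52 (88.4% kept) with the Y-linked level as a covariate. With the erythroid level as a covariate it was −1.71 (99.8% kept), but that level hardly differed between the groups. Mean log2 CPM of the erythroid list per library was 3.01 to 3.83 in wild type and 3.1 to 3.77 in strong CKO. The covariate could therefore not test an unequal share of blood. Blood that only diluted the lung RNA would shift both lists the same way. The opposite shifts of the endothelium and airway lists, without overlap between libraries, argue against it as the sole cause of the gap. A loss of endothelial cells or a larger share of airway in a small lung, lower expression per cell, and tissue taken along with the lung are candidate explanations that were not tested, and whole-lung RNA cannot separate them.

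Between strong and weak CKO the erythroid list differed by a median of 0.81, the platelet list by 0.83, the inflammatory list by 0.43, the striated muscle list by 0.33, the germline list by 0.3 (adjusted p = 8.8e-07), the airway list by 0.23, the cell cycle list by 0.19, the nerve list by 0.14 and the heme and iron list by 0.14. The capillary list differed by −0.28, the mesenchyme list by −0.23, the endothelium list by −0.21, the alveolar type 2 list by −0.2, the alveolar type 1 list by −0.15, the pericyte list by −0.13 and the hypoxia list by −0.09. The interferon list differed by 0.49 (adjusted p = 0.000893), and by −0.33 without MUT_S_860_3, and it was not called without MUT_W_549_3 (0.37). With the library number as a block it changed sign, while 2 of the other lists lost the call and 14 kept it. The call was lost for the germline list without MUT_W_549_3 (0.1), for alveolar type 1 without MUT_W_265_2 (−0.04), for pericytes without MUT_S_265_5 (−0.05), for striated muscle without MUT_S_265_5 (0.13), and for hypoxia without MUT_W_265_2 (−0.08), MUT_W_549_3 (−0.06) or MUT_S_268_4 (−0.03). It was lost for heme and iron without WT_549_2 (0.14), MUT_W_265_2 (0.15), MUT_W_549_3 (0.06) or MUT_S_265_5 (0.1), and for nerve without WT_265_1 (0.14), MUT_W_265_2 (0.22), MUT_W_549_3 (0.13), MUT_S_265_5 (0.12) or MUT_S_268_4 (0.22).

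For the counts against wild type, 1 of 10 splits of the 6 libraries gave as many genes for weak CKO (2054 in the 6-library fit, highest other 4) and 1 of 10 for strong CKO (4265, highest other 0), and 10 splits are too few for a share under 0.05. For all CKO against wild type, 1 of 84 splits of the 9 libraries gave as many (5131, highest other 7), the real grouping itself. That share lies under 0.05 and makes chance unlikely if all 9 libraries are exchangeable. Library numbers shared between groups and the uneven sex of the embryos leave their exchangeability open. Splits with as many shared numbers parted are fewer and were not counted separately here.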

How the results depend on the processing

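The Y-linked level as a covariate and leaving out X and Y genes were chosen only after the data were seen. Of 2335 values of 107 genes in weak CKO under the alternatives 2128 kept direction and side of the threshold, 190 lost the call, 8 gained it and 9 changed sign, and of 2600 values of 119 genes in strong CKO these counts were 2454, 136, 8 and 2. Between the CKO groups 14 of 342 values of 16 genes changed sign. DESeq2 gave no adjusted p for 6 named values, and Y-linked genes have no value with the Y-linked covariate. Of 30 lists 13, 12, 17 and 13 were called in weak, strong, strong against weak and all CKO, 11 to 14, 12 to 15, 13 to 19 and 11 to 14 when a library was left out, and 1, 1, 0 and 0 with the estimated correlation, which widens the variance of a list. By fry 11, 13, 0 and 12 were called. All CKO against wild type stayed between 3431 and 5523 genes. Where no cause is given, the cause was not tested.

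Leaving out each library in turn gave 1310 to 2828 genes in weak CKO, 3101 to 4983 in strong CKO, 1 to 4 in strong against weak CKO, and an overlap of 1281 to 2606, in fits with fewer libraries. The interferon list in strong against weak CKO ranged from −0.33 to 0.85. Ranges in weak CKO were −0.13 to 0.01 for Cd79b and −0.51 to 0.02 for Hba-a1, and in strong CKO −0.24 to 0.01 for Cd79b and −0.05 to 0.53 for Gzma. In strong against weak CKO they were −0.01 to 0.71 for Scgb1a1, −0.13 to 0.10 for Dnmt1, −11.54 to 0.44 for Ddx3y and −0.02 to 0.57 for Xist.

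With the erythroid level as a covariate 1452 genes were called in weak CKO and 0 in strong against weak CKO (1465 at an unadjusted p under 0.05, with 14 by DESeq2 without the covariate). Of 107 named weak CKO values with this covariate 66 kept direction and side of the threshold, 34 lost the call and 7 changed sign. It changed the sign in weak CKO of Ddx58 (0.31), Stat2 (0.38), Itgb3 (0.20), Hbb-bs (0.14), Hba-a2 (0.30), Hba-a1 (0.52) and Hbb-bt (0.06), and in strong against weak CKO of Vcam1 (−0.06), Scgb3a2 (−0.06), Scgb1a1 (−0.06) and Dnmt1 (0.22). The haemoglobin genes are part of that covariate. The erythroid level was 2.38 to 2.98 in weak CKO, below all libraries of wild type (3.01 to 3.83) and strong CKO (3.1 to 3.77). The covariate was thus tied to both contrasts with weak CKO, so calls lost with it cannot be read as effects of blood. With the Y-linked level as a covariate 2914 genes were called in strong CKO, the overlap of weak and strong effects was 1729 and Xist in strong against weak CKO was −2.17. An adjusted p under 0.01 gave an overlap of 1024. Strong against weak CKO had 4 genes with only the groups compared, 14 in DESeq2 and 2 on the log2(RPKM + 0.1) scale.

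With the library number as a block, 3 genes were called in strong against weak CKO, while weak CKO had 3926 and strong CKO 4450 genes. The interferon list (−0.36), Vcam1 (−0.02), Dnmt1 (0.07) and Xist (−0.95) changed sign in strong against weak CKO. Of the 17 lists called there, 14 kept the call and 2 lost it. Residual expression of 7 same-numbered pairs of libraries correlated at −0.09 to 0.35, with 4 over 0.1, and 6 of 8 libraries correlated best with a same-numbered one, which does not establish that they were littermates. Small changes could be missed at this depth and spread, since 53.7% of simulated 1.5-fold changes were recovered in weak CKO.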

Other observations

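Tests on MUT_W_268_3 were set up after its Xist and Y-linked RNA had been seen. That of a mixed library was chosen only after the result was seen. Beyond the fixed lists, 306 genes rose more than 8-fold in both CKO groups and 6 fell, by fitted changes that depend on the prior count where wild type reads were absent. Of the risers, 112 had 0 counts in the wild type libraries, 197 had at most 3, and 148 exceeded 1 CPM in every CKO library, while 23 belonged to any fixed list and 20 to the germline list. Genes picked from them afterwards include the meiotic recombination gene Mnd1 (2.87, 62.6 and 81.6 CPM in wild type, weak and strong CKO), the potassium channel gene Kcnh1 (5.26, 60.3 and 67.5 CPM), the testis ribosomal protein gene Rpl39l (0.0879, 20.7 and 25.8 CPM) and the cadherin gene Cdh19 (0.23, 31.4 and 33.5 CPM).

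Of these 306 genes 60 lay on the X chromosome. All 60 were higher in MUT_W_268_3, which held Y-linked RNA, than in both wild type libraries with Y-linked RNA. Values of MUT_W_268_3 had a part in selecting them. The risers included 17 olfactory receptor genes, 15 Rhox homeobox genes, 7 Mage genes, 5 Xlr genes and 3 vomeronasal receptor genes, families counted after the list was seen. No enrichment is given, because most of the 306 genes had at most 3 wild type counts and so passed the count filter through the CKO libraries. Clustered families share sequence, so counts of their members are not independent.

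MUT_W_268_3 held Xist at 956 CPM, 272 times the mean of both wild type libraries with Y-linked RNA. This was 40.9% of the mean of the 6 libraries without Y-linked RNA, and 37.2% to 46% of the single libraries among them. A mixture of male and female tissue or RNA would lower Y-linked genes by 0.76 on the log2 scale, and it is argued against by their median log2 ratio of 0.004 to the wild type libraries (−0.04 to 0.03 over 4 genes). Xist made in Y-bearing cells of a CKO lung is a candidate explanation. Whether it silenced their X chromosome cannot be told apart from no silencing. The X minus autosome difference over 421 X-linked genes was −0.071, while the largest within 5 pairs of same-sex libraries of a group was 0.079 in size. Weak CKO against wild type libraries, both without Y-linked RNA, gave −0.1. An embryo with an extra X chromosome was not tested and remains open.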
